A study of Mus musculus with 2 samples.

How the data were processed

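Total RNA of mouse liver, 1 wild type and 1 Drp1 knockout sample, was amplified, labelled with Cy3 and hybridised to Agilent Whole Mouse Genome arrays, per the labels' protocols. Both samples lay on 1 slide, so the slide does not separate the groups. Spot values are fluorescence intensities that Agilent Feature Extraction produced, per the file headers: the processed signal used here is background-subtracted and spatially detrended, with a small positive substitute for spots near background. The submitters' processing notes name version 9.5.1.1 of that program, while the file headers name module version 10.7.1.1. The deposited value table holds intensities on a linear scale. Its sorted values are equal in both columns at all but 221 ranks, with a greatest gap of 0.0417%, as quantile normalization gives. Both columns have a median of 45.9, and each has a Spearman correlation of 0.9999 with the scanner values of its array over 39429 probes, so its scale and direction are known and it was used as an alternative. All columns of the value table belong to the 2 samples.

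Each array held 44397 spots, of which 1377 were controls and were left out. The other 43020 spots covered 39429 probes, 399 of them in 10 copies. Spots marked as non-uniform or as population outliers were left out (183 on the wild type and 190 on the knockout array), and 0 spots were saturated. Signals were log2-transformed after division by the array's 75th percentile over non-control spots, and copies of a probe were averaged on the log2 scale. A probe counted as measured on an array where at least 50% of its usable spots were marked well above background. A gene's difference is the mean over its probes measured on both arrays. Of 3357 genes with several such probes, 1 had probes at least 2-fold apart from 0 in opposite directions. Of the 117 genes with several probes and a 2-fold difference, 110 had probes of the same sign throughout.

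For genes with no probe measured on both arrays and a probe well above background on 1 of them, a lower bound is given as "at least N-fold". It sets the bright array's value against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array, and the probe with the greatest bound stands for the gene. No bound is given where both arrays were below background.

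Probes were named through the accession in the files with a table of RefSeq genes of assembly GRCm38.p6, which was used for names only. It named 26761 probes by accession and 4453 by symbol or synonym, and for 8215 the file's own name was kept. Probe positions are those of the files, in mm9. They were not converted, and exon or UTR annotation was not used here.

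With 1 array per group no test between the groups was possible, and no p-value or SE is given. The number of arrays limits the precision. The SD between spots of the same probe was pooled over 241 measured probes with several spots and describes measuring error on an array, not variation between mice. The differences reported are counts of genes at least 2-fold apart, single genes, and medians of 40 gene lists that were fixed before the data were examined. Each list's median was placed among the medians of 10000 random lists of the same size drawn from the same 20 bins of mean signal, and a list stands apart below the 2.5th or above the 97.5th percentile. Members count as higher or lower from 1.5-fold. Dnm1l was left out of all lists.

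The genes named were set by a rule made before the data were examined. It takes Dnm1l and Fgf21, the 15 genes with the greatest positive and the 15 with the greatest negative difference among genes above the median signal whose probes share a sign, the 5 greatest lower bounds in each direction, and in each list up to 5 measured members with the greatest difference. Genes without a symbol were passed over, and a gene that the rule names is not reported here. Ddit3, Gdf15, Atf4 and Alb, the sex-linked genes, the fat tissue genes below background, Ucp1, Fabp4, Ckm, Myh4, Cela2a, Dlk1 and further muscle and list genes in the closing part were named in addition, after their values were seen.

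The alternatives fixed before the data were examined were quantile normalization, centring on the median of measured probes, loess normalization (span 0.3), normexp background correction with an offset of 50 on the raw signals, no filter on dim probes, a stricter filter that keeps probes above the 25th percentile of measured probes on both arrays, the brightest probe per gene, and the deposited value table. Scaling to the E1A spike-in spots was added after seeing the data. The median of all measured genes moved by 0.11 under loess normalization and by -0.20 without the filter, and by less than 0.1 under the other settings fixed beforehand.

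The gene counts were tested on simulated arrays built from the mean levels of the 15385 measured genes and the spot errors of each array, for the comparison of knockout against wild type. All 200 genes given a difference were called 2-fold in the right direction (50 each at 2.0, -2.0, 1.5 and -1.5 log2 units), and 0 of the other genes were. The list percentiles were tested on the measured differences themselves. Of 200 lists of 25 random genes, 12 fell outside the central 95% of their matched lists, and 50 of 50 lists raised by 0.5 were found. The simulated error of a difference was 0.14, far below the 2-fold cut, and random genes do not vary together as related genes can. These tests therefore check the calculation and not how often real differences or lists would be called wrongly. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1 for normexp.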

Results

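RNA from the livers of 2 male C57BL/6J mice was profiled on 1-colour Agilent mouse genome arrays. One group was wild type and the other was a knockout of Drp1, the dynamin-related GTPase that divides mitochondria, encoded by Dnm1l. Both mice had eaten a lard-based high-fat diet (24% fat, 45% of its energy) for 24 weeks from 4 weeks of age. Each group held 1 array, so no difference below has a replicate check and none was tested between the groups. The labels do not say whether the livers were taken after a fast or after refeeding. A difference in feeding state between the 2 mice was therefore not tested for any gene below. Differences are given as log2 values, knockout minus wild type, or as folds, and levels as multiples of the 75th percentile of an array's own signals. Of 39429 gene probes, 19918 (50.6%) were well above background on the wild type array and 22513 (57.1%) on the knockout array. Both arrays measured 19470 probes of 15385 genes, across which the log2 levels correlated at r = 0.98 (across probes, which are not independent replicates). Spots of the same probe differed by an SD of 0.11 log2 units on the wild type array and 0.08 on the knockout array. By this spot error alone, a difference between the arrays carried an SD of 0.14, or 1.1-fold. It leaves out error between labellings, hybridisations and probes of a gene, and the spread between animals. The 8 probes of Gapdh, for example, ran from -0.52 to -0.07.

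The comparison asked how the liver transcriptome of the knockout differed from the wild type after prolonged high-fat feeding, with Dnm1l as the targeted gene and Fgf21, a liver hormone that acts on whole-body metabolism, as the gene named in the study's title. Fgf21 was 5.98-fold higher in the knockout (log2 difference 2.58), at 20.2 times the 75th percentile against 3.37 in the wild type. Its probe, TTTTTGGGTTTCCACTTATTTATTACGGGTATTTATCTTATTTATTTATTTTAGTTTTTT, lies on chromosome 7 at 52869305 to 52869364 (mm9), at position 842 of the transcript as the array's design counts it. Dnm1l differed by -0.21, or 1.16-fold lower in the knockout, at 1.75 times the 75th percentile against 2.03. Its single probe, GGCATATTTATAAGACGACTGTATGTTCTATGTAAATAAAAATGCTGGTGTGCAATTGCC, lies on chromosome 16 at 16312331 to 16312390 (mm9), at position 3993 of the transcript. The labels do not say which part of the gene was deleted, so this probe does not check the knockout label. Both arrays carried Y-linked Ddx3y and Eif2s3y well above background, and Xist was not well above background on either, which matches the male sex given for both mice.

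Across the genome, 447 genes were at least 2-fold higher in the knockout and 560 were at least 2-fold lower, so that 44.4% of these genes were higher. After loess normalization, which removes a dependence of the difference on brightness, the numbers were 502 and 408, with 55.2% higher. They were 211 and 301 with normexp background correction, 210 and 300 with a stricter filter on dim probes and 1574 and 1766 with none. Scaled to spike-in spots, a choice made after seeing the data, they were 3701 and 101, with 97.3% higher. At least 4-fold, 69 genes were higher and 75 lower. At least 8-fold, 13 were higher and 24 lower. The median difference of all measured genes was -0.11, with medians from -0.30 in the brightest to 0.02 in a dimmer group when genes were divided into 10 groups by level. A further 2168 genes were well above background on the knockout array alone and 374 on the wild type array alone. Of these, 347 were at least 2-fold higher and 339 at least 2-fold lower by the bound that the background sets. The lowest log2 level well above background was -4.08 on the wild type and -4.76 on the knockout array. A bound is thus reached more easily for lower than for higher genes, and these counts are not directly comparable.

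**Figure D1:**
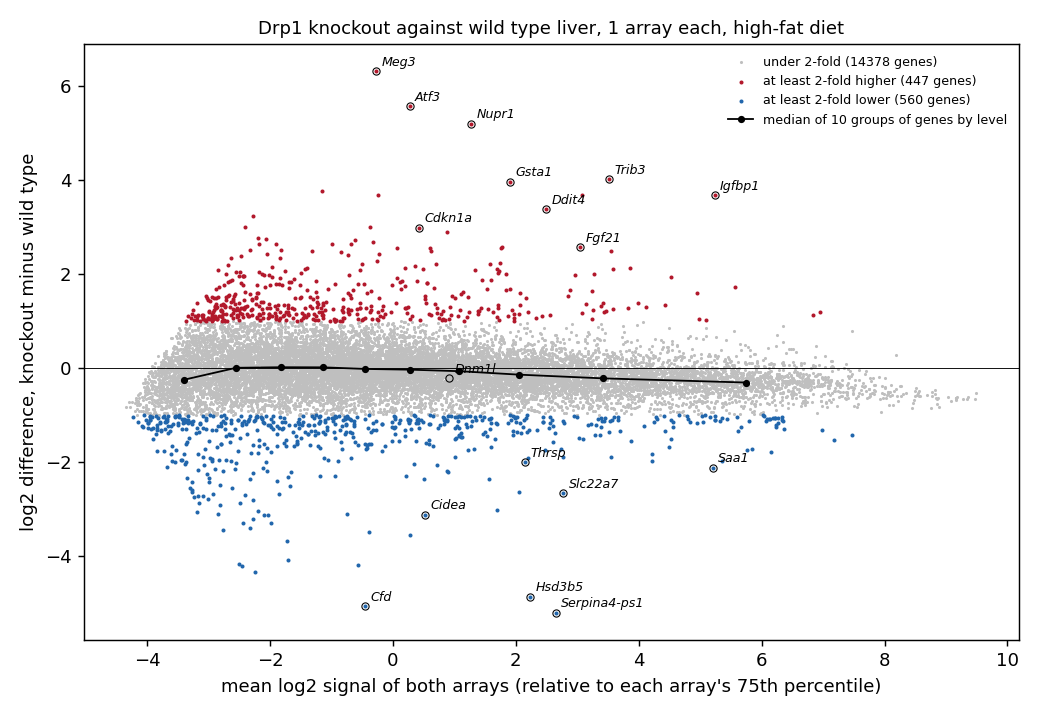
Log2 difference between the knockout and the wild type array (vertical axis) against the mean log2 signal of both arrays (horizontal axis, relative to each array's 75th percentile), 1 point per gene measured on both. Red and blue points are the 447 genes at least 2-fold higher and the 560 at least 2-fold lower, the black line joins the medians of 10 groups of genes by level, and circled genes are named in the text.

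Among well-expressed genes, those with the greatest positive differences included stress-response transcripts. Atf3, a stress-induced transcription factor, was 47.8-fold higher in the knockout, Nupr1, a chromatin-associated stress protein, 37.0-fold, and Trib3, a pseudokinase induced by Atf4 and Chop, 16.2-fold. Ddit4, an inhibitor of mTORC1, was 10.5-fold higher and Cdkn1a, the cell-cycle inhibitor p21, 7.98-fold. Igfbp1, a secreted protein that binds insulin-like growth factors, was 12.8-fold higher, at 135 times the 75th percentile against 10.5. The glutathione transferase Gsta1 was 15.7-fold higher, Ly6d 12.9-fold, Arhgef2 5.88-fold, the immediate early gene Egr1 5.85-fold and Cib3 5.63-fold. Interferon-inducible genes also stood among the 15 with the greatest positive differences, with Ifi27l2b 7.48-fold higher, Oas1f 5.95-fold and Oas1a 5.94-fold. The probes of Oas1a and Oas1f, and those of the Gsta genes, target families of closely similar transcripts, so the values of single members are uncertain. Among genes well above background on the knockout array alone, Psat1, an enzyme of serine synthesis, was at least 22.0-fold higher, S100g at least 21.9-fold, Nrg1 at least 17.6-fold, the non-coding RNA Mirg at least 11.4-fold and Oas3 at least 10.9-fold.

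Among well-expressed genes, here those above the median signal, the greatest negative differences were of mixed kinds, including a steroid dehydrogenase, lipid droplet proteins and a transporter. Serpina4-ps1 was 36.8-fold lower in the knockout, with both of its probes on chromosome 12 (mm9 105325060 to 105325127) between -5.23 and -5.18. The 2 probes overlap, so their values do not check each other independently. Hsd3b5, a male-specific steroid dehydrogenase, was 29.2-fold lower, the antisense RNA Hnf4aos 11.8-fold, the lipid droplet protein Cidea 8.67-fold, the ubiquitin ligase Rnf186 8.08-fold and the organic anion transporter Slc22a7 6.31-fold. Clstn3 was 6.21-fold lower, Fitm1, which acts in lipid droplet formation, 5.14-fold, Tpm2 5.11-fold, Dct 4.89-fold and the small nucleolar RNA Snora47 4.60-fold. Saa1, an acute phase protein whose probe resembles Saa2, was 4.33-fold lower, Usp2 4.14-fold, the sodium channel subunit Scnn1a 4.14-fold and the lipogenic regulator Thrsp 3.99-fold. The 5 genes with the greatest lower bounds on this side were all of striated muscle. Tnnc2 was at least 88.1-fold lower in the knockout, Tcap at least 36.5-fold, Acta1 at least 28.6-fold, Myh8 at least 27.3-fold and Tnnt3 at least 25.2-fold. The wild type array thus carried skeletal muscle transcripts that were not well above background on the knockout array, and Tpm2 is also a muscle gene.

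In all, 40 gene lists were fixed before the data were examined, and the median of each was set against 10000 random lists matched on brightness, as a description of these 2 arrays. By this measure 14 lists lay above their matched range, 12 below and 14 within. Members are counted as higher or lower when they differed by at least 1.5-fold.

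Targets of the integrated stress response, driven by Atf4 and Chop, were higher in the knockout, with 18 of 29 measured members higher and 2 lower. Their median was 0.68, above all 10000 matched lists. Besides Atf3, Nupr1, Trib3 and Ddit4, asparagine synthetase (Asns) was 13.7-fold higher, Chop itself (Ddit3) 4.26-fold, Gdf15 2.36-fold and Atf4 1.72-fold. By contrast, endoplasmic reticulum chaperones and degradation factors had a median of -0.48, below all matched lists, with 0 of 29 higher and 7 lower. Calr was 2.36-fold lower, Dnajb11 2.02-fold, Sdf2l1 1.92-fold, Hyou1 1.86-fold and Pdia3 1.76-fold. Nrf2 targets lay above all matched lists (median 0.28, 9 of 22 higher and 0 lower), led by Gsta1, by Cbr3 at 6.43-fold, by Gstm3 at 5.61-fold (its 2 probes gave 1.22 and 3.75 log2) and by Gsta2 at 4.03-fold. The p53 and apoptosis genes had a median of 0.37, above all matched lists, with 7 of 23 higher and 0 lower. After Cdkn1a, Gadd45a was 6.24-fold higher, Phlda3 3.42-fold, Trp53inp1 2.88-fold and the death receptor Tnfrsf10b 2.84-fold. Immediate early genes lay above all matched lists too (median 0.71, 10 of 16 higher and 0 lower), with Klf6 3.65-fold, Btg2 3.44-fold, Myc 3.09-fold and Nr4a1 1.89-fold higher. Cytosolic heat shock genes stayed within their matched range (median -0.27, 25.1st percentile), and 0 of 15 differed by 1.5-fold. Their members ranged from Cryab at 0.52, whose 2 probes gave -0.39 and 1.43, to Ahsa1 at -0.46, Stip1 at -0.43, Bag3 at -0.41 and Fkbp4 at -0.40.

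Among mitochondrial genes, subunits of oxidative phosphorylation were lower in the knockout. Of 76 measured, 0 were higher, 21 were lower and 55 lay between, with a median of -0.49 that was below all matched lists. Atp5j was 1.80-fold lower, Atp5k 1.75-fold, Ndufb3 1.70-fold, and Uqcr11 and Ndufa2 1.65-fold each. These are bright genes, for which the matched lists themselves had a median of -0.29, and after loess normalization the median of the list was -0.17. Mitochondrial chaperones and proteases lay at the 98.1st percentile of their matched lists with a median of 0.02, and 17 of 18 members differed by less than 1.5-fold. Clpx was 1.91-fold higher, Oma1 1.40-fold and Hspa9 1.37-fold, while Phb (-0.25) and Pmpca (-0.21, from probes at -0.69 and 0.27) were slightly lower. This call ended under quantile, loess and normexp processing and with the deposited value table. The other fission and fusion genes had a median of -0.13 (45.5th percentile), with 2 of 15 lower, Mtfp1 at 1.79-fold and Fis1, an outer membrane receptor, at 1.51-fold, next to Inf2 (-0.46) and Mief2 (-0.41). Mitophagy and autophagy genes had a median of -0.17 (43.8th percentile), with Sqstm1, the autophagy receptor p62, 1.91-fold higher, Optn 1.46-fold higher, Tfeb 1.55-fold lower, Map1lc3a 1.42-fold lower and Ulk2 1.40-fold lower.

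In lipid metabolism, fatty acid and triglyceride synthesis genes were lower, with 10 of 29 lower, 3 higher and a median of -0.35 (0.32nd percentile). Srebf1, the lipogenic transcription factor, was 3.14-fold lower, Aacs 2.66-fold and fatty acid synthase (Fasn) 1.96-fold. The list lay within its matched range under the stricter filter on dim probes and with the brightest probe per gene. Fatty acid oxidation and PPARa targets went both ways, with 6 of 40 higher, 7 lower and a median of -0.15 (97.3rd percentile, and above the matched range under the stricter filter). Within this list Acot2 was 5.53-fold higher, Ehhadh, of peroxisomal beta-oxidation, 3.31-fold and Pdk4 2.37-fold, while Acot3 was 3.04-fold lower and Ppara itself 2.18-fold lower. Cholesterol genes lay within their matched range (median -0.03, 4 of 25 higher and 4 lower), with Sqle 3.15-fold and Srebf2 1.82-fold higher and Stard4 2.63-fold, Ebp 1.86-fold and Insig1 1.82-fold lower. Lipid droplet and uptake genes did as well (median -0.25, 3 of 23 higher and 6 lower). Cidea, Fitm1 and Plin4 (2.05-fold) were lower, but Cidec was 3.70-fold and Lpl 1.97-fold higher. Cidea and Lpl also belong to the adipocyte list below, so these values do not tell liver cells from fat tissue. Genes of gluconeogenesis and insulin signalling had a median of -0.26 (21.8th percentile), with Igfbp1 and Tat (2.06-fold) higher and Socs3 (2.00-fold) and Pcx (1.70-fold) lower. Bile acid genes had a median of -0.23 (32.2nd percentile), with Abcc4 2.36-fold and Nr0b2 1.62-fold higher and Cyp7b1 2.53-fold, Slco1a1 1.84-fold and Abcg8 1.66-fold lower.

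Most genes listed for the growth hormone axis were lower in the knockout. Of 14 measured genes of growth hormone and Stat5 signalling, 0 were higher and 10 lower, with a median of -0.92 below all matched lists. Onecut1 was 3.73-fold lower, Socs2 3.12-fold, Lifr 2.78-fold, Igfals 2.59-fold and Cish 2.22-fold. Male-biased liver genes, many of which depend on pulsatile growth hormone, had a median of -0.63, below all matched lists, with 13 of 23 lower and 2 higher. After Hsd3b5, Keg1 was 3.22-fold and Nudt7 2.85-fold lower, whereas the near-identical Cyp4a12a and Cyp4a12b read 2.60-fold and 2.62-fold higher. Female-biased genes went both ways (median -0.07, 7 of 20 higher and 7 lower), from Ntrk2 at 4.30-fold higher to Cyp2b13 at 3.15-fold, Acot3 at 3.04-fold and Abcd2 at 2.57-fold lower. Xenobiotic metabolism genes had a median of -0.49 (0.020th percentile), with 13 of 27 lower and 4 higher. Cyp2b10 was 2.55-fold, Sult5a1 2.40-fold, Ces2a 2.37-fold and Cyp2c38 2.28-fold lower. The list lay within its matched range under quantile normalization and with the deposited value table. Hormones and carriers secreted by the liver had a median of -0.08 but a mean of 0.30, with 10 of 26 higher and 7 lower. Igfbp1, Fgf21, Gpnmb (5.38-fold) and Fst (3.96-fold) were higher, and Hamp2 was 2.95-fold lower. This list lay at the 96.6th percentile, and above the matched range in 4 of the 8 alternative settings fixed beforehand.

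Acute phase proteins were lower, with a median of -0.57 below all matched lists and 12 of 27 lower against 2 higher. Saa2 was 3.94-fold lower, Saa4 2.94-fold, Itih4 2.31-fold and Cxcl1 2.28-fold. Neutrophil markers had a median of -0.69 (0.060th percentile), with 5 of 8 lower, among them Retnlg at 3.02-fold, S100a9 at 2.16-fold, S100a8 at 2.06-fold, Camp at 1.62-fold and Lcn2 at 1.61-fold. Interferon-stimulated genes were higher, with 19 of 35 higher, 0 lower and a median of 0.85 above all matched lists. Ifi44 was 6.28-fold, Ifit2 4.61-fold, the chemokine Cxcl10 4.23-fold and the antiviral protein Rsad2 4.03-fold higher.

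Markers of several other liver cell types were higher in the knockout. Stellate cell and fibrosis genes had a median of 0.81, above all matched lists, with 17 of 27 higher and 1 lower. The collagens Col6a3 and Col1a1 were 3.44-fold and 3.19-fold higher, Pdgfra 3.06-fold, Lum 2.79-fold and Ccn2 2.61-fold. Macrophage and Kupffer cell markers had a median of 0.42, above all matched lists, with 15 of 31 higher and 1 lower. Trem2 and Gpnmb, genes of lipid-associated macrophages, were each 5.38-fold higher, Marco 3.14-fold, Cd14 3.03-fold and Ccl2 2.84-fold. Markers of bile duct and progenitor cells had a median of 0.84 (99.99th percentile), with 8 of 12 higher, including Anxa13 at 5.21-fold, Spp1 at 2.64-fold, Sox9 at 2.37-fold and Cdh1 at 2.01-fold, while Onecut1 was lower. T, B and NK cell markers had a median of 0.33 (99.99th percentile), with 7 of 19 higher and 2 lower, led by Ccl5 at 4.06-fold, Ptprc and Jchain at 2.29-fold and Cd3d at 1.98-fold, against Cd6 at 1.82-fold lower. Under the stricter filter on dim probes the last 2 lists kept only 5 and 13 members and lay within their matched ranges, at medians of -0.15 and -0.09. Endothelial markers lay within their range (median 0.02, 85.8th percentile), with 3 of 24 higher, namely Cd34 (1.99-fold), Lyve1 (1.91-fold) and Pecam1 (1.78-fold), then Oit3 (1.30-fold) and Emcn (1.41-fold, reversed in sign by normexp).

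Cell cycle genes were also higher, with a median of 0.53 above all matched lists and 10 of 22 higher against 2 lower. Cyclin D1 (Ccnd1) was 3.95-fold, Cdc20 2.49-fold, Cdk1 2.38-fold and Mcm2 2.26-fold higher, and the repressor E2f8 was 2.98-fold lower. Under the stricter filter on dim probes, 13 members were left and the list lay within its matched range.

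Genes of hepatocyte identity and secretion had a median of -0.47 (0.17th percentile), with 11 of 32 lower and 3 higher. The pioneer factors Foxa1 and Foxa2 were 2.14-fold and 1.71-fold lower, Hpd 1.65-fold lower and Alb 1.43-fold lower, while Tat was 2.06-fold and Foxa3 1.61-fold higher. Under quantile normalization and with the deposited value table this median was 0.00 and 0.01 and the list lay within its matched range, while after loess normalization the median was -0.11, still below its range. Pericentral genes had a median of -0.56 (0.010th percentile) and a mean of -0.17, with 7 of 17 lower and 2 higher. Slc1a2 was 2.55-fold, Cyp2c37 2.14-fold and glutamine synthetase (Glul) 1.90-fold lower, against Gstm3 and Rhbg (2.31-fold) higher, and the list lay within its range under quantile, loess and deposited values. Periportal genes lay at the 99.0th percentile with a median of -0.03 and a mean of 0.08 (median 0.26 under quantile, 0.25 under loess, 0.02 under normexp and 0.26 with deposited values), including Sox9, Aldh1b1 (2.23-fold) and Cdh1 higher and Pigr (2.00-fold) and Ctsc (1.54-fold) lower. Fetal liver genes were measured for 4 members only, with a median of 1.44 (99.97th percentile). Meg3, a maternally expressed non-coding RNA, was 79.9-fold higher by its 1 probe measured on both arrays, dim in the wild type at 0.092 times the 75th percentile. Its other probes, not well above background on the wild type array, read 16.2-fold and 12.2-fold higher. Those folds divide by wild type values near background (0.053 and 0.013 times the 75th percentile), so their size is uncertain. In the knockout these probes read 0.86 and 0.16 times the 75th percentile, against 7.36 for the first probe. Alpha-fetoprotein (Afp) was 3.88-fold and Cd24a 1.91-fold higher, while H19 was 1.84-fold lower.

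Markers of blood and of tissues near the liver also differed. Red blood cell genes had a median of -0.72 (0.010th percentile), with 6 of 10 lower, from Slc4a1 at 12.9-fold to Alas2 at 1.96-fold, Hba-a2 at 1.90-fold, Hbb-bt at 1.77-fold and Hba-a1 at 1.73-fold, whose globin probes resemble each other. Adipocyte markers had a median of -0.90 over 6 measured members (0.020th percentile). Cfd, the protease adipsin, was 33.6-fold lower, Cidea 8.67-fold and Car3 3.42-fold lower. Lpl was higher, Fabp4 was at 0.01 and Lipe at -0.03 (positive after loess normalization). With Ucp1, well above background on the wild type array alone, at its bound, the median was -1.77. Adipoq, Lep and Plin1 were not well above background on either array. The list of pancreas and muscle markers had a median of -0.26 over 5 measured genes, from Ctrb1 at 1.84-fold and Ins2 at 1.60-fold lower through Cel (-0.26) to Amy2a5 (0.05) and Clps (0.12, negative under normexp). With the 6 members seen on 1 array at their bounds, its median was -0.88. Among these 6, the muscle genes Acta1, Ckm, Myh4 and Tnnt3 and the pancreas gene Cela2a were well above background on the wild type array alone. Without the filter on dim probes this list lay below its matched range.

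Genes of the circadian clock had a median of -0.28 (3.62nd percentile), within the matched range but below it in 5 of the 8 alternative settings, with 2 of 17 higher and 5 lower. Arntl (Bmal1) was 4.31-fold higher, while Usp2 and the PAR-domain factors Dbp (3.55-fold), Hlf (2.41-fold) and Tef (2.00-fold) were lower. The study's design places its experiments in the morning after a fast, with other samples after refeeding. The labels of these arrays do not name the state, and whether the 2 livers matched in feeding state and hour is not known here. That limit also holds for Fgf21, Igfbp1 and the lipid genes above.

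Ribosomal protein genes had a median of -0.18, above the matched median of -0.30 for genes of their brightness (99.5th percentile), and 0 of 41 differed by 1.5-fold. The median was positive under quantile (0.11), loess (0.15) and deposited values (0.11), and above the matched range in each. Rps15 (-0.46) and Rpl22 (-0.36) were lower under the 5 scalings fixed beforehand, while Rpl10 (-0.37) and Rps14 (-0.35) turned positive under quantile, loess and deposited values and Rps29 (-0.34) under loess. Housekeeping genes lay within their range (median -0.09, 94.4th percentile), with Actb 1.66-fold lower as the 1 member of 14 past 1.5-fold, Gapdh at -0.35, Polr2a at -0.29, Hprt at 0.35 and Ywhaz at 0.39.

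The size of several list medians depended on the scaling. Under quantile and loess normalization, in that order, the medians were -0.29 and -0.29 for endoplasmic reticulum chaperones, -0.22 and -0.23 for acute phase proteins, -0.21 and -0.28 for male-biased genes, -0.45 and -0.44 for red blood cell genes and 0.52 and 0.53 for Nrf2 targets, each still outside its matched range. They were -0.14 and -0.15 for xenobiotic genes and -0.07 and -0.13 for pericentral genes. Under normexp, the medians were 0.12 for T, B and NK cell markers, 0.25 for bile duct markers, 0.20 for cell cycle genes, 0.34 for immediate early genes and 0.70 for fetal genes, each still above its matched range.

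**Figure D2:**
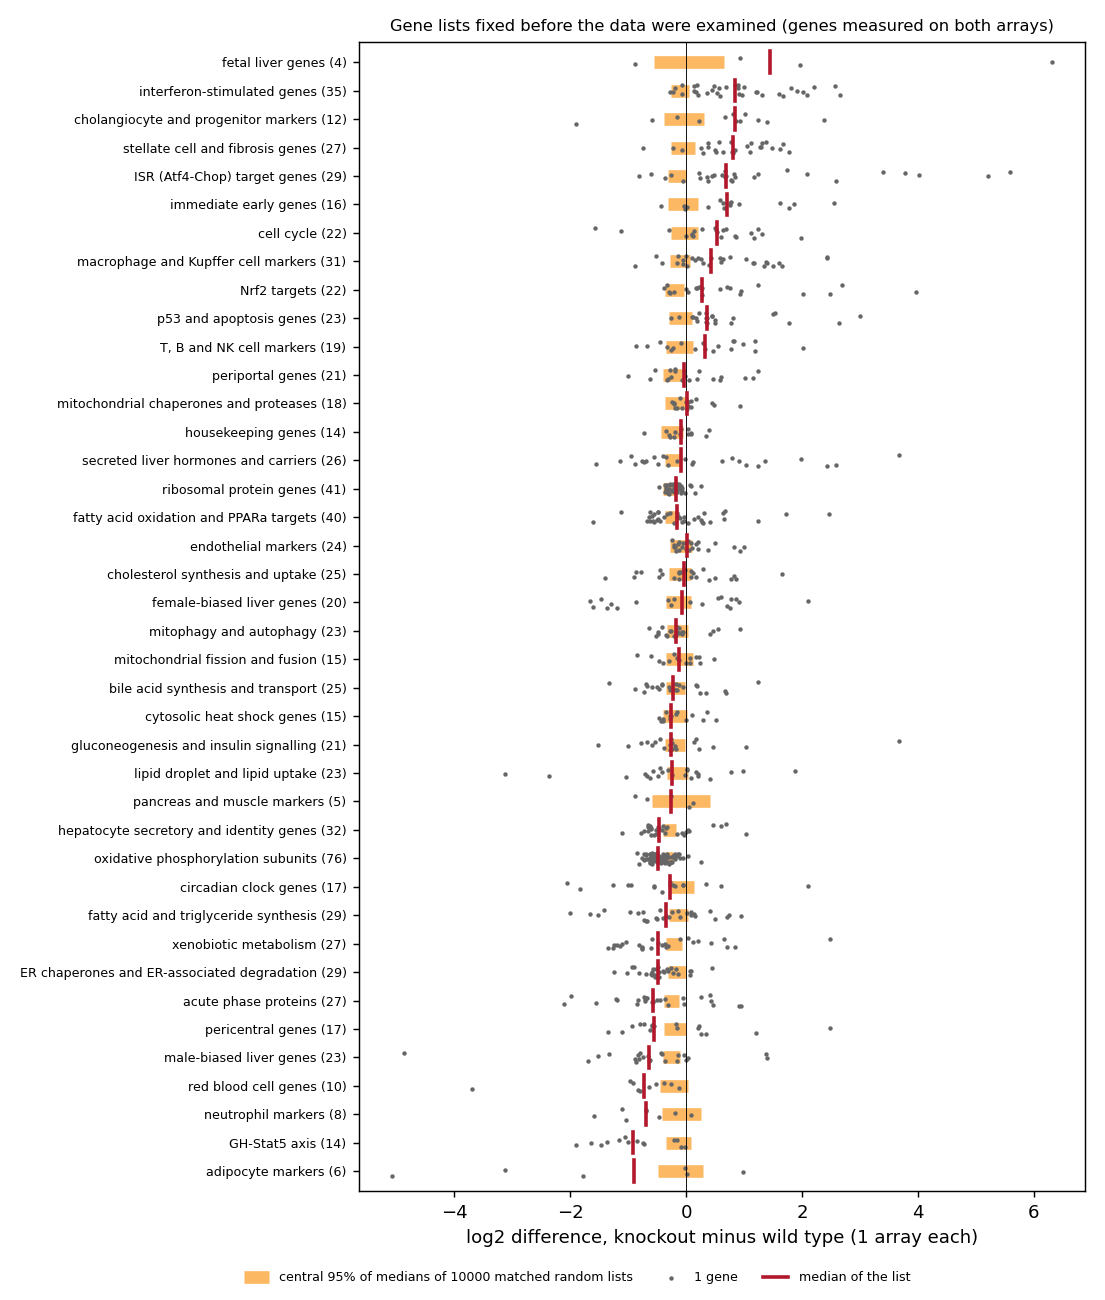
Log2 difference between the knockout and the wild type array (horizontal axis) for each gene measured on both arrays (grey points) in 40 gene lists and their medians (red bars), with the central 95% of medians of 10000 brightness-matched random lists (orange bands). The stress response list (median 0.68) and the interferon list (0.85) lie right of their bands, and the growth hormone list (-0.92) and the oxidative phosphorylation list (-0.49) lie left of theirs.

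All these differences are relative to each array's 75th percentile, whose raw signal was 461 on the wild type array and 722 on the knockout array, a ratio of 1.57. Against the E1A spike-in spots, RNAs added in known amounts during labelling, the median gene was 0.69 log2 units higher on the knockout array. Scaling by them, chosen after seeing the data, would add 0.80 to every difference.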

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

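The E1A spike-in spots, control RNAs outside the scaling by the 75th percentile, gave a different offset between the arrays than the genes did. This comparison was chosen only after the result was seen. Over the 7 of 10 spike-ins well above background on both arrays, the knockout array read -0.15 log2 units relative to the wild type array (SD 0.058 between spike-ins). The 75th percentile of gene probes was 0.65 higher there, and the median measured gene was 0.69 higher against the spike-ins. Scaled to them, 3701 genes were at least 2-fold higher in the knockout and 101 at least 2-fold lower. The amounts of RNA that were labelled are not given in the sources used here, so the data do not say whether the offset lies in the livers or in the labelling, and no biological explanation was tested.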

How the results depend on the processing

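No paired analysis was possible because each group held 1 array. The Dnm1l difference moved by less than the spot error of 0.14 under all settings fixed beforehand that measured it. Fgf21 was 2.74 under quantile and 2.77 under loess normalization and 2.73 with the deposited table, against 2.58. Genes at least 2-fold higher and lower numbered 211 and 301 with normexp, which adds an offset of 50 to the signals, 1574 and 1766 without the filter (408 and 509 of them shared with the 447 and 560), and 210 and 300 under the stricter filter, which leaves 11488 genes. With the spike-ins, chosen after seeing the data, they numbered 3701 and 101. The other settings gave 454 to 502 higher and 408 to 570 lower. Of 1547 values of named genes under alternatives, 1234 moved by less than the spot error, 313 moved by more, and 0 of the genes with a 2-fold difference changed sign.

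Lists above and below their matched ranges numbered 10 to 14 below and 11 to 14 above. Of the 14 above and 12 below, 9 and 8 stayed on their side under all 8 settings. The fetal list had no member under the stricter filter, which gave no value. Among the lists outside their matched ranges, medians changed sign for hepatocyte genes (0.0039 under quantile, 0.0105 with the deposited table; against matched lists 0.0015 and 0.0079), periportal genes (0.26 under quantile, 0.25 under loess, 0.017 under normexp, 0.26 deposited), ribosomal protein genes (0.11, 0.15 under loess, 0.11 deposited), T, B and NK markers (-0.091, stricter filter) and bile duct markers (-0.15, against matched lists -0.12, stricter filter with 5 genes left). Some lists within their ranges changed sign too, such as housekeeping genes (-0.13 to 0.13) and fatty acid oxidation (-0.24 to 0.07). With the spike-ins, which add 0.80 to all lists alike, the medians of ER chaperones (0.32), oxidative phosphorylation (0.31), fatty acid synthesis (0.45), xenobiotic (0.31), male-biased (0.17), acute phase (0.23), neutrophil (0.11), red cell (0.081), hepatocyte (0.33), pericentral (0.24), periportal (0.77) and ribosomal genes (0.62) were positive. Apart from the added offsets and the fewer genes, the cause was not tested. Genes not well above background on an array have only a bound there.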

Other observations

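Some members of the lists outside the rule for named genes add to the picture of the liver. In the stress response list, Phgdh was at least 3.48-fold and Mthfd2 at least 2.39-fold higher in the knockout, while Shmt2 was 1.75-fold lower. In the growth hormone axis, Ghr, the receptor, was 1.67-fold lower and Igf1, its circulating effector, 1.65-fold lower. Bcl6 was 2.06-fold lower, but Jak2 (-0.09), Stat5a (-0.21) and Stat5b (-0.01) were nearly level. The list describes transcript levels, and the activity of the pathway was not measured. Among fibrosis genes, Mmp2 was at least 4.23-fold and Tgfb2 at least 3.56-fold higher, and Acta2, a marker of activated stellate cells, was 1.75-fold higher. Among Nrf2 targets, Nqo1 was 1.93-fold and Hmox1 1.69-fold higher, but 13 of 22 measured members differed by less than 1.5-fold. These included Gclc (-0.0024), Gclm (-0.28), Txnrd1 (0.17) and Prdx1 (-0.33). Pck1 (1.38-fold) and Cpt1a (1.34-fold), of gluconeogenesis and mitochondrial fatty acid import, were slightly higher, while Scd1, a desaturase of fatty acid synthesis, was 1.65-fold lower.

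For the patterns that follow, all tests were chosen only after the results were seen. Each rests on 1 array per group, and a difference between the genotypes or between the individual mice stays open throughout.

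Skeletal muscle genes, and some fat tissue genes, marked the wild type array. Of 24 muscle genes listed, 13 were well above background there and at least 2-fold higher than on the knockout array, among them Tnnc2, Tcap, Acta1, Tnnt3, Mb (at least 24.3-fold) and Myl1 (at least 20.5-fold); 11 were well above background on the wild type array alone, and 7 also on the knockout array. RNA of skeletal muscle in the wild type sample is a candidate explanation that remains open. Ttn, Mylpf, Actn3 and Ampd1, abundant in muscle, were not well above background on either array and Atp2a1 was 1.04-fold apart, yet how well those probes bind is not known here. RNA of fat tissue stays open as well: 0 of the 4 markers Adipoq, Lep, Plin1 and Retn were well above background on the wild type array, yet 4 of 8 other adipocyte genes (Cfd, Cidea, Car3 and Ucp1) were at least 2-fold higher there. Others went against it, as Fabp4 was level (2.43 times the 75th percentile in the wild type, 2.45 in the knockout). Lipe differed by -0.03 and Lpl was 1.97-fold higher in the knockout. Car3 was also bright in the knockout, at 38.6 against 132 in the wild type. The test first excluded fat tissue from the absent markers alone. Its bar was changed to include the other genes after both results were seen, because genes near background exclude nothing.

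Markers of stellate cells, macrophages and bile ducts were higher in the knockout. A lower share of hepatocyte RNA, with the other cell types in unchanged proportions, would raise their markers alike. The stellate list exceeded the endothelial list by 0.78 (95% interval 0.48 to 1.15 by resampling members). That interval treats the genes of 1 pair of arrays as independent. Neutrophil markers were lower, with a median of -0.69 over 8 members, but Lcn2 among them is also on the acute phase list. Red blood cell genes were lower as well (median -0.72), so the neutrophil value does not bear on the hepatocyte share alone. The stellate and endothelial values argue against an even rise only. A lower hepatocyte share together with uneven shifts of the other cells stays open. A brightness-dependent difference between the arrays is argued against for the stellate list, since after loess normalization its median was 0.81, outside the central 95% of matched lists (-0.19 to 0.20). As the random lists were matched on brightness from the start, loess adds little to that comparison. The macrophage and bile duct medians were then 0.54 and 0.88, also above their ranges. The bile duct list depends on dim probes, with a median of -0.15, within its range, under the stricter filter. An effect of the knockout on these cells, a hypothesis, and variation between the mice were not tested.

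The Dlk1-Meg3 imprinted region on chromosome 12 (mm9 110698502 to 110987628) was higher in the knockout. An error of a single probe is argued against, since 6 of the 7 probes of Dlk1, Meg3 and Mirg were well above background on the knockout array and at least 2-fold higher there. The region lies on another chromosome than Dnm1l, which is on chromosome 16. Serpina4-ps1, 36.8-fold lower in the knockout, also lies on chromosome 12 (mm9 105325060 to 105325127). Whether the genotype or the individual mouse sets the difference of the Dlk1-Meg3 region stays open, and strain segments on chromosome 12 were not tested.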
